A study of Mus musculus with 6 samples.

How the data were processed

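RNA was measured in short-term hematopoietic stem cells (ST-HSC), a multipotent progenitor population with limited self-renewal, sorted from the bone marrow of C57BL/6J mice. Per the labels, the sort kept lineage-negative, Kit-positive, CD48-positive and CD150-negative cells, and 3 samples came from wild-type (WT) mice and 3 from mice expressing dnTCF4, a dominant-negative form of the TCF4 transcription factor. The gate as labelled does not name Sca-1. The genotype labels read dnTCF4-/- for the WT samples and dnTCF4+/+ for the dnTCF4 samples. The series description speaks of 3 mice of each genotype, so the libraries of a group were treated as separate animals. Per the labels' protocols, complementary DNA was made with a SMART-Seq v4 kit and libraries with Nextera XT, and sequencing was paired-end on an Illumina NextSeq instrument. This chemistry does not mark the strand of a transcript.

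The authors deposited a single table of RPKM values (reads per kilobase of gene length, scaled to the counted reads of the library), with 53677 gene symbols in rows and 1 column for each of the 6 libraries. Per the submitters' processing notes, STAR, featureCounts, DESeq2 and edgeR and the builds mm10 and GRCm38 were used. Their roles and versions, the gene annotation and the treatment of reads that map to several genes are not given in the sources used here. Columns were assigned to samples by the names in the sample descriptions. Of the symbols, 49804 were matched to the GENCODE M21 annotation of GRCm38, which gave coordinates and gene types. A further 183 symbols outside GENCODE matched a RefSeq synonym and were given neither. By gene type, 427 genes of the table were immunoglobulin genes.

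Depth was recovered from the values. RPKM multiplied by the union exon length in GENCODE M21 fell on whole multiples of 1 step per library, within a tolerance of 0.02 of a read, for 94.5% to 95.2% of the genes checked. The step gave 63500000, 61800000 and 67700000 counted reads for WT replicates 1, 2 and 3, and 63100000, 110900000 and 57400000 for dnTCF4 replicates 1, 2 and 3. At the lowest depth, 1 RPKM on a gene of 1 kb stood for 57.4 reads. The limit set by a count of 0 was taken as 3 reads per library. Such limits cover counting error only, because amplified reads without molecular identifiers are not independent molecules. No pair of libraries of a group agreed within sampling noise (the lowest chi-square per gene was 137), and none was treated as a duplicate.

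Genes with a mean of at least 1 RPKM over the 6 libraries were tested, on log2(RPKM + 1), with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided). Genotype was the only term, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. A log2 fold change on this scale is dnTCF4 minus WT and understates the change of genes near the pseudocount. An exact permutation test of 3 libraries against 3 cannot give a p below 0.1, and was run for a few single values. Gene lists were fixed before the data were examined. The 27 lists with at least 3 tested genes were tested with camera (limma, preset correlation 0.01), adjusted over the lists. The lists cover Wnt targets and components, granulopoiesis regulators, granule proteins, stem cell, lymphoid and erythroid-megakaryocyte genes, the cell cycle, CDK inhibitors, interferon, NF-kB, immediate early, ribosomal, ribosome biogenesis, mitochondrial, respiratory chain, glycolysis, cholesterol and unfolded protein response genes, and markers of 8 other cell types. The lists of sort-gate genes and sex-linked genes were described without a test. Limma recovered 66 of 100 genes simulated with a 2-fold change between dnTCF4 and WT and 100 of 100 with a 4-fold change, with 8 false calls among 10006 genes. In a simulation of the same comparison with the interferon genes raised 1.5-fold, camera called that list and 0 other lists of 27. In both simulations each gene varied independently of the others, while the correlation estimated in the real mitochondrial list was 0.81. They therefore do not show how often camera calls lists of correlated genes. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

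The genes named were chosen by a rule also fixed before the data were examined. It takes Tcf7l2, Csf3r, 5 further Wnt pathway genes and the sort-gate genes, the 10 largest rises and falls among called genes whose 3 values of each genotype do not overlap, and up to 4 members of each list with the smallest p. Igkc and Ighm come in through the lists. Of the 10 falls, 2 variable segments are given by value and without their names. Genes named outside the rule were chosen after their values were seen, and are given as such.

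The samples carry replicate numbers 1 to 3 in both genotypes. Deviations of same-numbered libraries from their group means correlated across genes at 0.17, 0.35 and 0.30 for numbers 1, 2 and 3, all above the bound of 0.1 set beforehand, so the numbers were taken to pair the samples. The pairing comes from these data and from no label, and the main fit does not use it. Y-linked transcripts were detected in replicate 1 of both genotypes and in no other library. Alternatives tried were other pseudocounts and filters, median ratio and quantile scaling, no mean-variance trend, library weights, a replicate block, leaving out each library, adjusted p under 0.1, and camera with an estimated correlation or fry in place of camera. Added after seeing the data were a covariate for Y-linked transcripts, use of replicates 2 and 3 only, removal of immunoglobulin genes with rescaling, and limma voom on recovered reads. For 2 tests in the closing section, each library was divided by its own share of reads outside immunoglobulin genes. Fold bounds against a group at 0 divide the lowest library of the other group by the RPKM of 3 reads, averaged over the libraries of the group at 0. The fits of Tcf7, Lef1, Apcdd1 and Bambi without a filter were added after seeing the data. The count models DESeq2 and edgeR were not run here, since the deposited values are RPKM.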

Results

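Poly(A) RNA of sorted ST-HSC was profiled in 6 libraries, with 3 mice per genotype (WT and dnTCF4). The comparison asked how the transcriptome of these progenitors differs when a dominant-negative TCF4, a form made to block transcription through β-catenin and TCF/LEF factors, is expressed. The study is known to be concerned with the G-CSF receptor and the making of granulocytes. Libraries held 61800000 to 67700000 counted reads in WT and 57400000 to 110900000 in dnTCF4, and 11326 genes reached the mean of 1 RPKM needed for testing. Across these genes, libraries of WT correlated at 0.95 to 0.96, libraries of dnTCF4 at 0.92 to 0.96, and libraries of different genotype at 0.87 to 0.95. The first principal component held 47.0% of the variance and placed the 3 WT libraries apart from the 3 dnTCF4 libraries, with dnTCF4 replicate 3 farthest out. Y-linked transcripts such as Ddx3y were read in replicate 1 of both genotypes (30.5 RPKM in WT and 24.8 in dnTCF4) and were listed at 0 in replicates 2 and 3.

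Tcf7l2, the gene that encodes TCF4 (GRCm38 chromosome 19, 55741820 to 55933654), was listed at 1.51 ± 0.20 RPKM in WT and 2.31 ± 0.42 in dnTCF4 (SD, n = 3 each). All 3 dnTCF4 values lay above the 3 WT values, with an exact two-sided permutation p of 0.1, the smallest possible with 3 against 3. The log2 fold change was 0.39 (SE 0.16) and did not pass the limma test (adjusted p = 0.52). It was 0.24 after median ratio scaling and 0.26 with immunoglobulin genes left out. The labels do not give the species or the extent of the transgene, so these reads check the genotype labels only as far as transgene reads were assigned to Tcf7l2.

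Of the 32 direct targets of Wnt signalling in the list fixed beforehand, 8 reached the mean of 1 RPKM needed for testing. Axin2, a negative feedback regulator of the pathway, was at 0.0391 ± 0.0137 RPKM in WT and 0.0334 ± 0.0387 in dnTCF4. Lef1 was at 0.0799 ± 0.0612 and 0.0174 ± 0.0163, Ccnd1 (cyclin D1) at 0.563 ± 0.107 and 0.751 ± 0.280, and Tcf7, which encodes TCF1, at 1.52 ± 1.10 and 0.468 ± 0.369. These 4 genes were below the mean of 1 RPKM and were not tested. Although their groups overlapped, Tcf7 (2.79 and 0.894, 0.888 and 0.278, and 0.895 and 0.232 RPKM in WT and dnTCF4 replicates 1, 2 and 3) and Lef1 were lower in dnTCF4 in each pair of libraries with the same number. Of the 22 targets that were in the table and not tested, 9 had a higher mean in dnTCF4, 10 a lower one and 3 the same. In every pair, 3 of these were lower (Tcf7, Lef1 and Apcdd1) and 1 higher (Bambi). Apcdd1 had means of 0.320 and 0.104 RPKM in WT and dnTCF4 and groups that did not overlap. Of the 8 tested targets, 4 were higher and 0 lower in every pair. With only 3 pairs, some of 22 genes would be lower in every pair by chance, so these counts do not establish a shift of the targets. In a limma fit without a filter, chosen after these values were seen, adjusted p was 0.69 for Tcf7, 0.70 for Lef1, 0.49 for Apcdd1 and 0.69 for Bambi, or 0.45, 0.50, 0.46 and 0.49 with the replicate block. Of the 8 tested targets, 6 had higher values in dnTCF4, against 3 of 9 after median ratio scaling and with immunoglobulin genes left out. Myc was at 21.2 ± 1.21 RPKM in WT and 22.2 ± 1.91 in dnTCF4 (log2 fold change 0.06, limma adjusted p = 0.87), a sign that turned after median ratio scaling (-0.16). Jun, a component of the AP-1 factor, was at 3.99 ± 0.602 and 8.87 ± 1.51 (log2 fold change 0.98, limma adjusted p = 0.14) and was the 1 member that passed when adjusted over the list alone, against 0 over all genes tested. Cd44 was at 44.8 ± 8.5 and 62.9 ± 8.13. The target list was not called by camera (adjusted p = 0.42). Its median log2 fold change was 0.12, against 0.14 for all genes tested, and was -0.16 after median ratio scaling and -0.13 with immunoglobulin genes left out. Of 26 tested components of the pathway, 23 had higher values in dnTCF4, against 15 of 27 after median ratio scaling and 16 of 27 with immunoglobulin genes left out. Among them were Aes at 3.76 ± 0.485 and 5.27 ± 0.976 RPKM and Bcl9 at 1.43 ± 0.203 and 2.04 ± 0.306. That list was not called either (adjusted p = 0.24).

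Csf3r, which encodes the G-CSF receptor (GRCm38 chromosome 4, 126024550 to 126044440), was at 118.2 ± 5.95 RPKM in WT and 75.3 ± 26.5 in dnTCF4 (SD, n = 3 each). The 3 dnTCF4 values lay below the 3 WT values, with an exact two-sided permutation p of 0.1. The log2 fold change was -0.71 (SE 0.29, 95% confidence interval -1.40 to -0.03). It did not pass the limma test after adjustment over all genes (adjusted p = 0.51). Without dnTCF4 replicate 3 the log2 fold change was -0.38, and with libraries weighted by their noise it was -0.43.

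Regulators of granulopoiesis were not called as a list. Of 21 tested regulators, 16 had higher values in dnTCF4, and Cebpb and Klf4, which encode transcription factors of the myeloid lineage, passed when adjusted over the list alone, while 0 members passed over all genes. Cebpb was at 0.600 ± 0.129 RPKM in WT and 1.62 ± 0.264 in dnTCF4, and Klf4 at 1.27 ± 0.0325 and 2.64 ± 0.456. Camera gave the list an adjusted p of 0.44, and its median log2 fold change of 0.16 was -0.04 after median ratio scaling. Of 22 tested granule protein genes, 15 had higher values in dnTCF4, with a median log2 fold change of 0.82. Lysozyme (Lyz2) was at 1190 ± 196 RPKM in WT and 2262 ± 430 in dnTCF4, and Cybb, a subunit of the phagocyte oxidase, at 11.5 ± 1.47 and 23.7 ± 5.20. These 2 genes passed when adjusted over the list alone, and 0 members passed over all genes. The granule list had a camera adjusted p of 0.059. It was called with the replicate block (adjusted p = 0.021), without WT replicate 2 (0.039), without WT replicate 3 (0.00028), after median ratio (0.0012) and quantile (0.00083) scaling, without a filter (0.030), with immunoglobulin genes left out (0.0029) and by voom (0.033). It was not called with an estimated correlation (adjusted p = 0.56), by fry (0.21), at a mean of at least 5 RPKM (0.12) or with library weights (0.11). Nor was it called without WT replicate 1 (0.13), without dnTCF4 replicates 1, 2 and 3 (0.071, 0.16 and 0.099) or with replicates 2 and 3 only (0.14). The highest value of the 6 libraries was in dnTCF4 replicate 3 for 14 of 22 members, and without that library the median was 0.74.

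Immunoglobulin transcripts made up the main difference between the genotypes. They took 44.1%, 26.7% and 25.5% of summed RPKM in WT replicates 1, 2 and 3, and 6.33%, 3.27% and 6.00% in dnTCF4 replicates 1, 2 and 3, which gives 32.1% ± 10.4 against 5.20% ± 1.68 (SD, n = 3 each, exact two-sided permutation p = 0.1). As a share of reads, they were 9.44% ± 4.22 against 1.22% ± 0.447. Of 232 tested immunoglobulin genes, 217 had lower values in dnTCF4, with a median log2 fold change of -2.80, which was -3.02 after median ratio and -2.67 after quantile scaling. Igkc, the kappa constant gene (GRCm38 chromosome 6, 70726435 to 70726966), fell from 51205 ± 19881 RPKM to 6697 ± 2654 (log2 fold change -2.96, SE 0.39, limma adjusted p = 0.042). Ighm, the mu constant gene (GRCm38 chromosome 12, 113418558 to 113422730), fell from 11319 ± 2107 to 1910 ± 768 (log2 fold change -2.65, SE 0.35, limma adjusted p = 0.042). Leaving out 1 library ended the call of Igkc in 6 of 6 fits (adjusted p = 0.057 to 0.13) and that of Ighm in all except the fit without dnTCF4 replicate 2 (0.038 to 0.16).

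**Figure D1:**
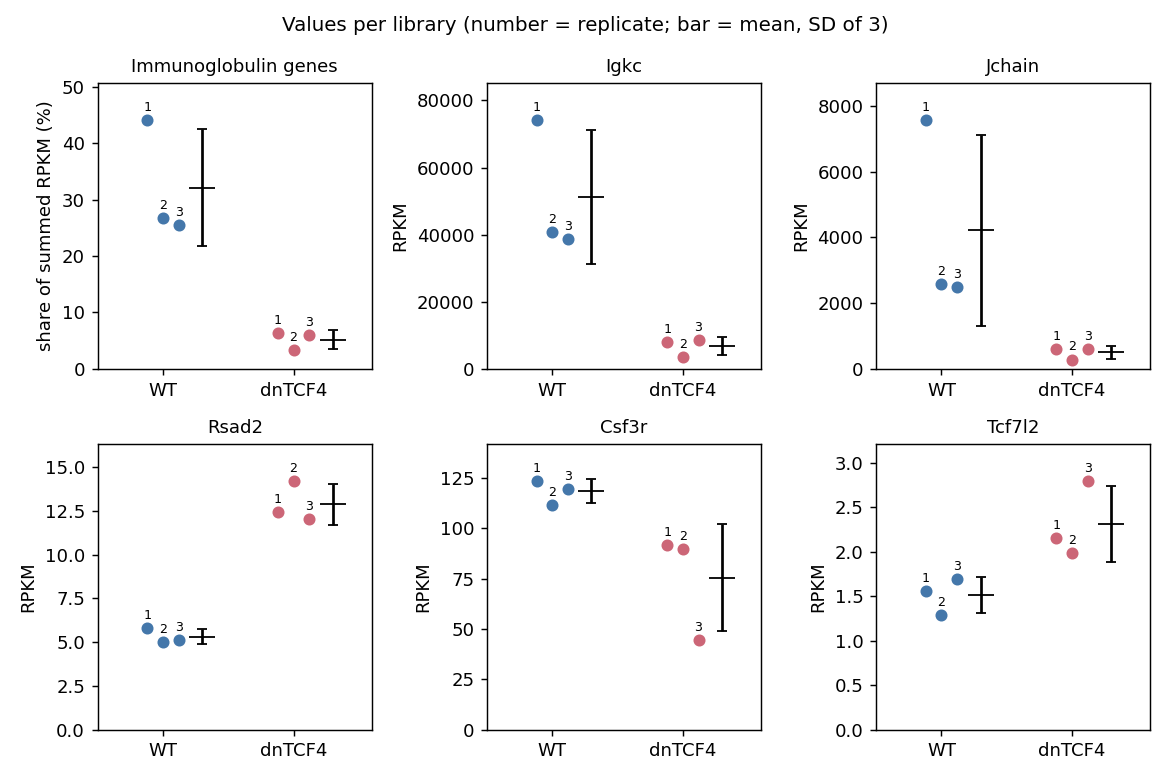
Values of each library, with the replicate number at each point and a bar for the mean and SD of 3 libraries per genotype. Panels give the immunoglobulin share of summed RPKM in percent and the RPKM of Igkc, Jchain, Rsad2, Csf3r and Tcf7l2. The immunoglobulin share lies between 25.5% and 44.1% in WT and between 3.27% and 6.33% in dnTCF4.

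In the whole transcriptome, 34 genes changed between the genotypes (limma, adjusted p under 0.05), of which 29 were lower and 5 higher in dnTCF4. All 29 lower genes were immunoglobulin genes, and the 5 higher ones were not. With the replicate block 49 genes changed, 42 of them lower. These were 35 immunoglobulin genes and 14 other genes, of which 7 were higher. The largest falls were in variable segments, which encode the antigen-binding part of antibodies. Igkv3-2 (GRCm38 chromosome 6, 70698449 to 70699067) fell from 696.7 ± 315 RPKM to 0.301 ± 0.0193 (log2 fold change -8.97, SE 0.31, adjusted p = 0.00011). Igkv5-39, Ighv5-6, Igkv3-4, Ighv1-42 and Igkv4-61 fell with log2 fold changes of -8.53, -7.54, -7.06, -6.59 and -6.43, and 2 further variable segments with -6.30 and -6.10. Ighv1-47 (79.9, 69.2 and 549.6 RPKM in WT replicates 1, 2 and 3) and Igkv8-34 (179.3, 71.5 and 127.0) were at 0 in all 3 dnTCF4 libraries. Against a floor of 3 reads per library there, the lowest WT library gives at least 650-fold lower values for Ighv1-47 and at least 617-fold lower values for Igkv8-34. Among these 10 segments, Igkv3-2, Igkv5-39, Ighv5-6, Igkv3-4 and Igkv8-34 passed in each of 6 fits that left out 1 library. Ighv1-47, Ighv1-42, Igkv4-61 and the 2 further segments lost their call in 3 to 5 of the 6, and Ighv1-42 also with the replicate block (adjusted p = 0.051). Variable segments resemble one another, so reads could be split between them and the value of a single segment is uncertain.

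Higher values in dnTCF4 were called for 5 genes. Kcne3, which encodes a potassium channel subunit, rose from 2.78 ± 0.494 RPKM to 9.35 ± 0.467 (log2 fold change 1.46, limma adjusted p = 0.034). Its reads cannot be told apart from those of an antisense gene that spans it. Clec4a3 and Clec4b1, C-type lectin receptor genes of myeloid cells, rose from 1.74 ± 0.580 to 7.41 ± 1.26 and from 1.89 ± 0.438 to 6.46 ± 0.632 (limma adjusted p = 0.046 for both). Gm29291, a long intergenic RNA, rose from 3.01 ± 0.106 to 9.74 ± 2.02 (log2 fold change 1.40, limma adjusted p = 0.049, and 0.066 with the replicate block). Gm24960, annotated as a small nuclear RNA gene, was at 0 in all WT libraries and at 2.17 ± 0.748 RPKM in dnTCF4, from 8 to 22 reads, at least 2.72-fold higher in the lowest dnTCF4 library against a floor of 3 reads per library. Each of these calls was lost in most fits that left out 1 library: Kcne3, Clec4a3, Clec4b1 and Gm29291 in 6 of 6, with adjusted p from 0.064 to 0.19, and Gm24960 in those without WT replicate 1 (0.13), WT replicate 2 (0.064) and WT replicate 3 (0.086). After median ratio scaling, 18 genes changed, of which 0 were higher and 18 lower.

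The count of 34 varied with the libraries used. Without WT replicate 1 it was 7, without WT replicate 2 it was again 34, of which 20 were shared, without WT replicate 3 it was 18, and without dnTCF4 replicates 1, 2 and 3 it was 22, 16 and 11. With immunoglobulin genes left out and the libraries rescaled, limma called 0 genes, with 603 at an unadjusted p under 0.05. Voom on recovered reads, with immunoglobulin genes kept, called 14. It tested 10004 genes, those whose values were whole reads in all libraries. In the deposited values 1090 of 11326 genes had an unadjusted limma p under 0.05, where chance would give 566. The excess was smaller after median ratio scaling (695 of 11262 genes) and with immunoglobulin genes left out (603 of 11091). The deposited values of the genotypes did not overlap for 17.7% of genes, where chance gives 10%. The median log2 fold change of all genes tested was 0.14. It was -0.05 after median ratio scaling and -0.02 with immunoglobulin genes left out, so counts of higher and lower members of a list depend on the scaling.

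Gene lists fixed beforehand were compared with all other tested genes. Camera called 13 of the 27, of which 8 were higher and 5 lower in dnTCF4, and 0 of the 13 with an estimated correlation. The list-wise test fry, which asks whether members move one way on balance, called 3, the interferon, erythroblast and CDK inhibitor lists. Other splits of the 6 libraries into 3 and 3 gave up to 8 called lists.

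Interferon-stimulated genes rose as a group in dnTCF4 (camera adjusted p = 5.3e-09, and adjusted p = 0.25 with an estimated correlation). Of 32 members, 29 had higher values, with a median log2 fold change of 0.54, which was 0.34 after median ratio scaling. Adjusted over the list alone, 18 members passed, against 0 over all genes tested. Rsad2, the antiviral protein viperin, was at 5.31 ± 0.433 RPKM in WT and 12.9 ± 1.16 in dnTCF4 (log2 fold change 1.14, limma adjusted p = 0.060). Ifi27l2a was at 76.8 ± 14.7 and 202.8 ± 47.3, Ifit3 at 2.07 ± 0.789 and 5.60 ± 0.207, and Oas2 at 2.54 ± 0.653 and 6.17 ± 0.894. The immunoglobulin share moved the other way in the same libraries, from 32.1% to 5.20%.

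**Figure D2:**
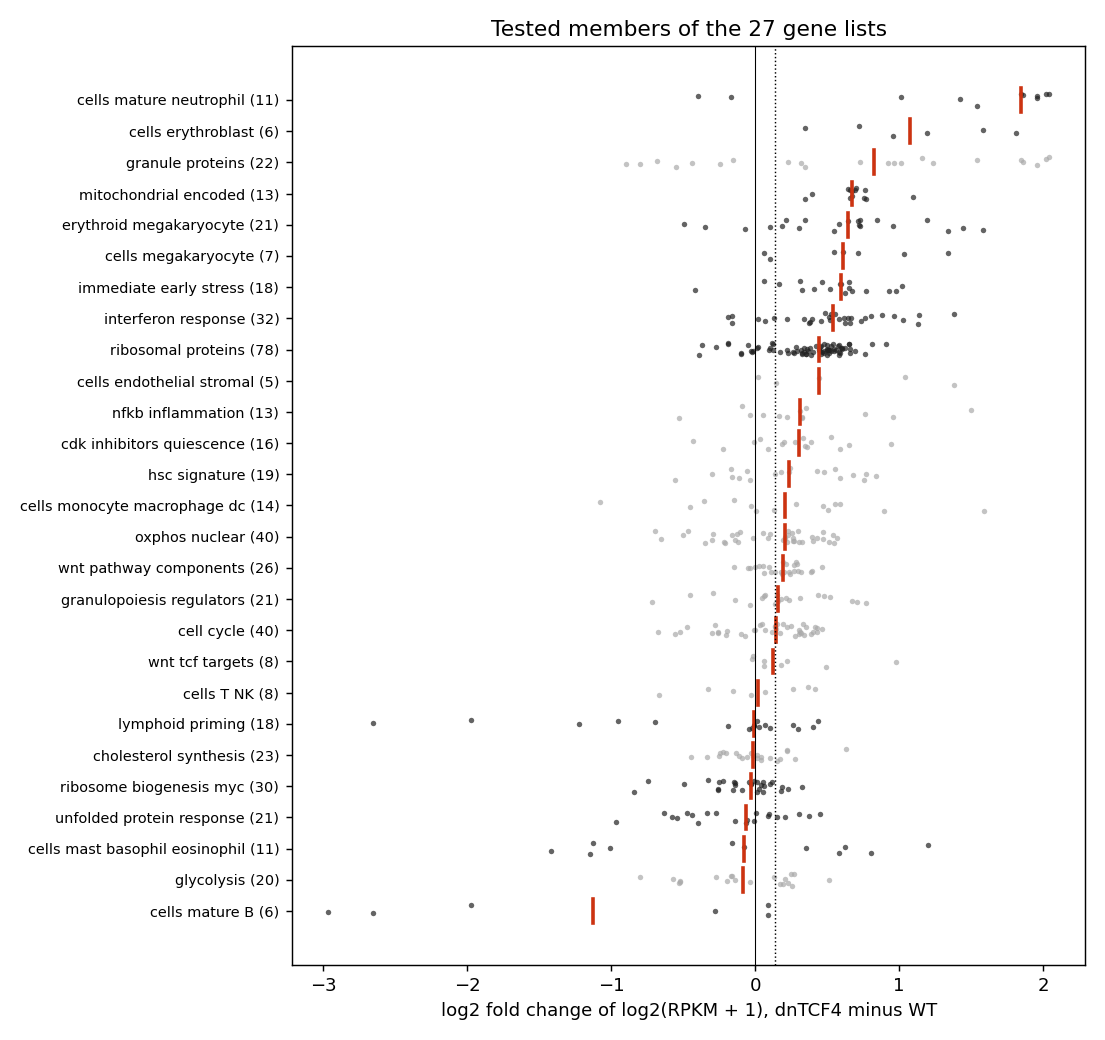
Log2 fold changes (dnTCF4 minus WT) of the tested members of 27 gene lists, 1 point per gene. Red bars are list medians, the dotted line is the median of all tested genes (0.14), and lists in dark have a camera adjusted p under 0.05. The interferon list has its median at 0.54 and the mature neutrophil list at 1.85.

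Genes of red cells and platelets were also higher as groups. The erythroblast list was called (camera adjusted p = 6.8e-05, and adjusted p = 0.25 with an estimated correlation), with 6 of 6 tested members higher in dnTCF4 and a median log2 fold change of 1.07. Rhag, a membrane protein of the Rh complex, was at 3.92 ± 0.670 RPKM in WT and 16.9 ± 6.30 in dnTCF4, Car2 (carbonic anhydrase) at 638 ± 27.7 and 1055 ± 116, and beta-globin Hbb-bt, uncertain because of its near-identical copy Hbb-bs, at 14.1 ± 4.67 and 46.0 ± 21.3. The megakaryocyte list was called (camera adjusted p = 0.0035, and adjusted p = 0.42 with an estimated correlation), with 7 of 7 members higher, or 5 of 7 after median ratio scaling. Pf4, platelet factor 4, was at 51.5 ± 10.1 and 131.2 ± 20.4, and Gp9 at 3.23 ± 0.831 and 5.96 ± 1.38. The broader erythroid-megakaryocyte list was called as well (camera adjusted p = 0.00058, and adjusted p = 0.47 with an estimated correlation), with 18 of 21 members higher, among them Rhd at 6.47 ± 2.98 and 18.1 ± 2.10. Adjusted over each list alone, 4, 4 and 7 members of these lists passed, against 0 over all genes. The 3 lists share members, so they are not independent of one another.

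Markers of mature neutrophils were higher in dnTCF4 as a list (camera adjusted p = 0.0048, and adjusted p = 0.56 with an estimated correlation), with 9 of 11 tested members higher, a median log2 fold change of 1.85 and 0 members passing when adjusted over the list alone or over all genes. S100a8, a calcium-binding protein abundant in neutrophils, was at 263.1, 232.4 and 1026 RPKM in WT replicates 1, 2 and 3 and at 1106, 1356 and 2948 in dnTCF4 replicates 1, 2 and 3. S100a9 was at 191.5, 234.6 and 1040.5 RPKM in WT and at 1040.3, 1168 and 2601 in dnTCF4, so the groups overlapped while each dnTCF4 library lay above the WT library of the same number. dnTCF4 replicate 3 held the highest value of the 6 libraries for 9 of 11 neutrophil markers. Without it the list median was 1.47, with 9 of 11 higher. Immediate early genes were called higher (camera adjusted p = 0.00070, and adjusted p = 0.42 with an estimated correlation), with 17 of 18 members higher. Klf4, Jun and Dusp1 passed when adjusted over that list alone and 0 members over all genes. Dusp1, a phosphatase of MAP kinases, was at 2.92 ± 0.820 and 6.86 ± 1.23, and Egr1 at 0.818 ± 0.308 and 2.15 ± 0.840. This list was not called among genes with a mean of at least 5 RPKM (adjusted p = 0.065).

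Ribosomal protein genes were called higher in dnTCF4 (camera adjusted p = 5.9e-06, and adjusted p = 0.56 with an estimated correlation), with 67 of 78 members higher and a median log2 fold change of 0.45, or 57 of 78 and 0.21 after median ratio scaling. Rps27 was at 499.4 ± 62.2 RPKM in WT and 866.2 ± 242 in dnTCF4, and Rpl37a at 328.5 ± 79.2 and 628.7 ± 209. Transcripts of the mitochondrial genome were called higher too (camera adjusted p = 6.8e-05, and adjusted p = 0.56 with an estimated correlation), with 13 of 13 members higher. The cytochrome b transcript mt-Cytb was at 2536 ± 383 and 4165 ± 1438, and the ribosomal transcript mt-Rnr1 at 184.3 ± 103 and 370.7 ± 130. In both lists dnTCF4 replicate 3 stood apart: it held the highest value of the 6 libraries for 50 of 78 and 13 of 13 members, with mt-Cytb at 3237, 3438 and 5822 RPKM and Rps27 at 758.1, 696.8 and 1144 in dnTCF4 replicates 1, 2 and 3. Without it the medians were 0.30 and 0.41, with 78 of 78 and 13 of 13 members higher (camera adjusted p = 1.5e-08 and 0.0012). The immunoglobulin share moved the other way between the genotypes, at 32.1% in WT and 5.20% in dnTCF4, and a link between it and these lists was not tested. In both lists 0 members passed when adjusted over the list alone or over all genes, and with replicates 2 and 3 only the ribosomal list was not called (adjusted p = 0.076).

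Markers of mature B cells were lower in dnTCF4 as a list (camera adjusted p = 2.5e-05, and adjusted p = 0.42 with an estimated correlation). Of 6 tested members 4 were lower, and Igkc, Ighm and Cd79a passed when adjusted over the list alone, against Igkc and Ighm over all genes. Cd79a, a chain of the B cell receptor complex, was at 40.4 ± 24.5 RPKM in WT and 10.7 ± 8.74 in dnTCF4. The list was not called once immunoglobulin genes were left out (adjusted p = 0.064). The lymphoid priming list was called lower (camera adjusted p = 0.0089, and adjusted p = 0.56 with an estimated correlation), with 10 of 18 members lower and Ighm the 1 member that passed, both over the list alone and over all genes. Blnk, an adaptor of B cell receptor signalling, was at 4.42 ± 1.99 and 1.57 ± 1.76. That call was kept in 11 of 21 alternatives. Besides fry and the estimated correlation, it was lost without WT replicate 1 (adjusted p = 0.87), without dnTCF4 replicate 2 (0.20), with library weights (0.52), after quantile scaling (0.15), at a mean of at least 5 RPKM (0.14), without a filter (0.069), with replicates 2 and 3 only (0.14) and with immunoglobulin genes left out (0.065).

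Unfolded protein response genes were called lower in dnTCF4 (camera adjusted p = 0.0035, and adjusted p = 0.42 with an estimated correlation), with 13 of 21 members lower and a median log2 fold change of -0.06, or 17 of 21 and -0.28 after median ratio scaling and 17 of 21 and -0.25 with immunoglobulin genes left out. Xbp1, a transcription factor of secretory cells, was at 14.9 ± 2.58 RPKM in WT and 9.42 ± 2.59 in dnTCF4, and the disulfide isomerase gene Pdia4 at 96.6 ± 18.5 and 54.1 ± 26.7. Ribosome biogenesis genes were called lower (camera adjusted p = 0.0089, and adjusted p = 0.56 with an estimated correlation), with 17 of 30 members lower, or 28 of 30 after median ratio scaling and with immunoglobulin genes left out. Nop56, a nucleolar protein, was at 134.1 ± 55.7 and 78.6 ± 38.7. That call was lost without WT replicate 2 (adjusted p = 0.078), after quantile scaling (0.19) and at a mean of at least 5 RPKM (0.12). In both lists 0 members passed when adjusted over the list alone or over all genes. Markers of mast cells, basophils and eosinophils were called lower (camera adjusted p = 0.045, and adjusted p = 0.56 with an estimated correlation), with 6 of 11 members lower, of which Prss34, Mcpt8 and Il5ra passed when adjusted over the list alone and 0 over all genes. The basophil proteases Prss34 and Mcpt8 were at 162.1 ± 66.5 and 56.8 ± 8.77 and at 105.1 ± 22.4 and 51.9 ± 11. The mast cell call was kept in 7 of 21 alternatives. Besides fry and the estimated correlation, it was lost with the replicate block (adjusted p = 0.12), without WT replicate 1 (0.41), WT replicate 2 (0.057) and dnTCF4 replicate 1 (0.50), after median ratio (0.34) and quantile (0.22) scaling, at a mean of at least 5 RPKM (0.36), without a filter (0.11), with the Y-linked covariate (0.092), with immunoglobulin genes left out (0.15) and by voom (0.080), and its direction turned with replicates 2 and 3 only (0.78). Without dnTCF4 replicate 3 the median of its members was 0.33 while camera still pointed down (0.046). The immunoglobulin share was also lower in the dnTCF4 libraries, at 5.20% against 32.1%, and a link between it and these 3 lists was not tested.

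The other lists were not called, and 0 of them were called with an estimated correlation. CDK inhibitors had a camera adjusted p of 0.061, with 13 of 16 members higher in dnTCF4. Cdkn2c was at 3.40 ± 0.331 RPKM in WT and 7.63 ± 2.06 in dnTCF4 and passed when adjusted over the list alone, and Btg1 was at 5.40 ± 1.22 and 8.56 ± 1.06. The list was called by fry (0.014), after median ratio scaling (0.023), with library weights (0.019), without a filter (0.039), with immunoglobulin genes left out (0.037), by voom (0.034), without WT replicate 1 (0.044) and without dnTCF4 replicate 3 (0.019). The stem cell signature had an adjusted p of 0.29, or 0.020 without dnTCF4 replicate 3 and 0.044 with library weights, with 12 of 19 members higher. Pdzk1ip1, a stem cell marker, was at 37.0 ± 3.91 and 66.9 ± 4.71 and passed when adjusted over the list alone. Cell cycle genes had an adjusted p of 0.38, or 0.044 without WT replicate 1 and 0.019 with library weights. For these camera pointed down while the median (0.14), the mean (0.07) and fry pointed up, and the median was -0.08 after median ratio scaling. Mcm3 was at 219.4 ± 64.9 and 151.7 ± 79.1, and Nusap1 at 73.9 ± 16.2 and 104.6 ± 32.8. NF-kB genes had an adjusted p of 0.35, or 0.044 without WT replicate 1, 0.019 without dnTCF4 replicate 3 and 0.025 with library weights. The chemokine Ccl4 was at 98.9 ± 69.6 and 253.4 ± 83.9. Glycolysis genes had an adjusted p of 0.075, or 0.037 without dnTCF4 replicate 1 and 0.049 with immunoglobulin genes left out, and the glucose transporter gene Slc2a3 was at 8.02 ± 1.13 and 5.46 ± 1.95. Cholesterol synthesis genes had an adjusted p of 0.15, or 0.021 without WT replicate 2, 0.035 after median ratio scaling and 0.032 with immunoglobulin genes left out, with camera, median (-0.01) and mean (-0.01) down and fry up. Their regulator Srebf2 was at 4.30 ± 0.278 and 7.22 ± 0.871. Nuclear genes of the respiratory chain had an adjusted p of 0.88 and a median of 0.21, which was -0.03 after median ratio scaling, and Ndufb3 was at 260.2 ± 14.3 and 383.3 ± 82.6.

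Among markers of further cell types, those of monocytes, macrophages and dendritic cells had a camera adjusted p of 0.53, with 9 of 14 members higher in dnTCF4 and a median of 0.21, which was -0.06 after median ratio scaling. When adjusted over the list alone, Cd209a and Adgre1 passed as higher and Cd74 as lower. The macrophage marker Adgre1 was at 1.10 ± 0.320 RPKM in WT and 2.90 ± 0.321 in dnTCF4, the dendritic cell lectin Cd209a at 10.8 ± 4.96 and 32.4 ± 6.30, and the class II invariant chain Cd74 at 712.2 ± 94.4 and 356.3 ± 157. T and NK cell markers had an adjusted p of 0.65, with camera and mean (-0.01) down and median (0.02) and fry up, and the T cell receptor gene Trbc1 at 12.1 ± 10.5 and 7.71 ± 8.02. Endothelial and stromal markers had an adjusted p of 0.36, or 0.019 without dnTCF4 replicate 3, 0.023 with library weights and 0.00064 without a filter, with 5 of 5 tested members higher, or 3 of 5 after median ratio scaling, and the osteoblast gene Bglap at 0.394 ± 0.490 and 3.56 ± 3.63.

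Genes of the sort gate did not pass the limma test. Kit was at 64.2 ± 18.3 RPKM in WT and 69.1 ± 31.2 in dnTCF4 (log2 fold change 0.03, limma adjusted p = 0.98), a sign that turned after median ratio scaling (-0.20). Cd48 was at 900.9 ± 90.6 and 1195 ± 209 (log2 fold change 0.40, limma adjusted p = 0.57), and all 3 dnTCF4 values lay above the 3 WT values. Slamf1, which encodes CD150, was at 0.931 ± 0.191 and 0.969 ± 0.218 and was below the mean needed for testing. Ly6a, which encodes Sca-1, was at 142.5 ± 80.7 and 120.6 ± 43.7 (log2 fold change -0.17, limma adjusted p = 0.87).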

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

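The covariate for Y-linked transcripts, the use of replicates 2 and 3 only, the removal of immunoglobulin genes and voom were chosen after seeing the data. The 34 genes became 61 at an adjusted p under 0.1, 6 without a filter, 18 after median ratio scaling, 86 with library weights, 10 with replicates 2 and 3 only, 0 with immunoglobulin genes left out, 14 with voom, and 7 to 34 when 1 library was left out. Removing immunoglobulin genes removes the 29 called among them, and the smaller library sets leave fewer samples. Voom could test only the 10004 genes with whole reads in all libraries, and how much of its shift came from this was not tested. The cause of the other shifts was not tested either. The replicate block gave 49 genes, 24 of them shared with the 34, and 13 lists. Among the named genes it ended the calls of Gm29291 and Ighv1-42 and added one for Mzb1 (adjusted p = 0.031), and among the lists it ended the mast cell call and added the granule list, and it changed no other call of a named gene or list. The 13 called lists became 0 with an estimated correlation and 3 with fry. Over the 21 alternatives of each, the 13 lists kept their call in 223 of 273 cases, and the 14 uncalled lists gained one in 31 of 294. Csf3r stayed negative in 19 alternatives (-0.94 to -0.38, adjusted p = 0.33 to 0.99) and Tcf7l2 positive in 17 (0.24 to 0.57, adjusted p = 0.26 to 0.99), with no call in any. Tcf7l2 had no value at a mean of at least 5 RPKM or with voom. The named called genes kept their direction in all 341 cases and their call in 216. Of 10 splits of the 6 libraries into 3 and 3, the real one gave 34 genes and 13 lists and the highest other 2 genes and 8 lists, and 10 splits are too few for a share under 0.05. Depth limits what can be said of Axin2 and Lef1, which lie far below the 1 RPKM that stands for at least 57.4 reads on a gene of 1 kb.

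Directions turned in these cases, all uncalled results except the mast cell list, and the cause was not tested. Log2 fold changes turned with library weights for Ly6a (0.15), Myc (-0.00024) and Trbc1 (0.12), after median ratio scaling for Kit (-0.20) and Myc (-0.16), with immunoglobulin genes left out for Kit (-0.17) and Myc (-0.13), and with replicates 2 and 3 only for Kit (-0.28) and Ly6a (0.0066). With 1 library left out, Kit ranged from -0.27 to 0.44 and Ly6a from -0.42 to 0.26. Lists whose direction turned had these adjusted p: with fry, cell cycle and T and NK cells 0.81 and cholesterol 0.83; after median ratio scaling, T and NK cells 0.93 and respiratory chain 0.94; after quantile scaling, T and NK cells 0.93; with library weights, T and NK cells 0.20 and respiratory chain 0.93. With replicates 2 and 3 only these were mast cells 0.78, monocytes 0.65 and respiratory chain 0.32. Granulopoiesis had 0.72 at a mean of at least 5 RPKM. The respiratory chain had 0.91 with the replicate block, 0.99 with the Y-linked covariate and 0.81 with immunoglobulin genes left out. Wnt targets had 0.47 without a filter and 0.92 with immunoglobulin genes left out. With 1 library left out, the adjusted p ranged from 0.044 to 1.00 for the cell cycle, 0.11 to 0.88 for T and NK cells, 0.18 to 0.83 for monocytes, 0.23 to 0.72 for granulopoiesis, 0.37 to 1.00 for the respiratory chain and 0.17 to 0.89 for Wnt targets.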

Other observations

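The tests of plasma cell markers, of scaling, of the deeper library, of reads taken by immunoglobulin transcripts and of the interferon list, and the genes named in this part, were chosen after the values were seen. The most abundant variable segments were the same in all 6 libraries. Ighv11-2 took 10.9% to 21.1% of heavy chain variable RPKM in WT and 11.9% to 21.6% in dnTCF4, and Igkv14-126 took 23.3% to 38.7% of kappa variable RPKM in WT and 22.6% to 36.2% in dnTCF4. These segments are known as a pair used by B-1 cells, a self-renewing B cell type. Both ranges overlap between the genotypes, while the level of Ighv11-2 was 4192 ± 373 RPKM in WT and 515.3 ± 167 in dnTCF4 (SD, n = 3 each). In contrast, 6 variable segments were at 50 RPKM or more in all WT libraries and under 1.5 in all dnTCF4 libraries.

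A cluster of C-type lectin receptor genes on GRCm38 chromosome 6, from 122921848 to 123289870, had higher values in dnTCF4. All 6 tested members (Clec4a1, Clec4a2, Clec4a3, Clec4b1, Clec4d and Clec4e) had non-overlapping values, with a median log2 fold change of 1.32, or 1.16 after median ratio scaling. Of these, Clec4a3 and Clec4b1 passed limma. Markers of monocytes, macrophages and dendritic cells went both ways, with 9 of 14 higher and a list not called by camera (adjusted p = 0.53), and neither an effect at this locus nor a change in the cells sorted was tested for this cluster. Clec4a2 was at 2.76 ± 1.28 RPKM in WT and 10.4 ± 1.71 in dnTCF4, and Clec4e at 27.2 ± 7.42 and 51.6 ± 7.68. In a limma fit with a term for Y-linked transcripts, 29 genes followed that term, 28 of them higher in the libraries with Y-linked transcripts, which are replicate 1 of each genotype. Besides Y-linked genes they include the lymphoid genes Dntt (642.7 RPKM in WT replicate 1 against 190.2 and 167.8 in WT replicates 2 and 3, and 354.2 in dnTCF4 replicate 1 against 91.1 and 86.6), Lck (59.9 against 21.04 and 19.66 in WT) and Ccr9 (2.86 against 0.271 and 0.289 in WT). Number and sex-linked transcripts cannot be separated here.

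Lower immunoglobulin transcripts in dnTCF4 were weighed against 3 technical explanations. Median ratio scaling moved the median log2 fold change of all tested genes only from 0.14 to -0.05. That of immunoglobulin genes went from -2.80 to -3.02, with an upper quartile of -1.74. A shift this small falls far short of the immunoglobulin falls. It also meant that the test could hardly have come out otherwise, so the test itself adds nothing against scaling by total reads. Of 16 plasma cell markers encoded outside the immunoglobulin loci, 14 were tested and 1 (Xbp1) is also in the unfolded protein response list. Their median log2 fold change was -1.11, below all 10000 random lists matched on expression (middle 95% from -0.03 to 0.30). Random lists hold unrelated genes, so this rank is no measure of the spread between mice. Of the 14, 13 were lower in dnTCF4 and 11 did not overlap, while Tnfrsf13b was higher and Sdc1 and Fkbp11 overlapped. The lowest limma adjusted p was 0.070 (Fam46c). These falls argue against variable segment haplotypes or shared reads as the whole cause. Antibody-secreting cells, or their RNA, among the sorted cells in larger amount in WT would give such falls. The most abundant markers were Jchain at 4214 ± 2905 RPKM in WT and 503.5 ± 190 in dnTCF4 and Mzb1 at 135.4 ± 68.8 and 24.8 ± 14.7. For Mzb1 the limma adjusted p was 0.14, or 0.031 with the replicate block and 0.027 with the Y-linked covariate. The lineage-negative, Kit-positive gate would be set to exclude antibody-secreting cells. Whether dnTCF4 changed the number of such cells in the marrow, or the sorts differed in purity, stays open and was not tested.

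Most other genes were slightly higher in dnTCF4, with a median log2 fold change of 0.14 and 69.8% of the 11094 tested genes outside the immunoglobulin genes above 0. The deeper library dnTCF4 replicate 2 is argued against, since the median without it was 0.15 over all tested genes and 0.16 over these. The shares of reads outside immunoglobulin genes predict a shift of 0.13, and with RPKM taken per those reads the median of other genes was 0.041 (quartiles -0.16 and 0.19) with 57.0% above 0, which is consistent with reads taken by immunoglobulin transcripts in WT as a candidate cause of part of the shift. This test replaced one whose rescaling centres the median by itself, it kept the bounds of that one, and the predicted shift was known when it was written. A change of total RNA per cell cannot be seen in RPKM and was not tested.

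The interferon list was higher in dnTCF4. Reads taken by immunoglobulin transcripts are argued against as the whole cause, because the list median was 0.44 with RPKM taken per reads outside immunoglobulin genes (quartiles 0.25 and 0.62), against 0.54 in the deposited values, where the read shares predict a shift of 0.13 (a test that replaced one against all other genes, which such a correction moves alike, and whose outcome could be estimated when it was written). dnTCF4 replicate 3, the library farthest from the rest, is argued against as well. Without it 31 of 32 members were higher, with a median of 0.60 (camera adjusted p = 2.8e-13 at the preset correlation). That p compares genes with genes and does not measure the spread between mice. Over the 21 alternatives of this list the highest adjusted p was 0.25, with an estimated correlation. More monocytes, macrophages or dendritic cells among the sorted cells cannot be told apart from a change within the progenitors, because their 14 tested markers went both ways, with a median log2 fold change of 0.21 and quartiles of -0.12 and 0.54, and an effect of the genotype itself may also contribute.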
